A study of Escherichia coli
Escherichia phage T7 with 30 samples.

How the data were processed

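RNA sequencing was done on Escherichia coli cultures infected with wild-type bacteriophage T7 at 25 °C. The labels name 3 biological replicates at each of 5 times (5, 10, 15, 20 and 25 min) and 2 technical runs of each, which makes 30 files. The design text of the series lists the times without 20 min, so the 20 min libraries rest on the sample labels alone. Total RNA was isolated with Trizol, per the labels' protocols. It was fragmented and reverse transcribed from random primers, second strands were made with a directional kit, and libraries were amplified by 10 rounds of PCR. The authors aligned the reads with HISAT2 and counted them with bedtools, per the submitters' processing notes. Versions, the treatment of reads that match several places and the strand setting are not given in the sources used here. The labels do not describe a step that removes ribosomal RNA. Each deposited file lists the features of the host annotation (a BL21 chromosome of 4528118 bp) and of the T7 annotation (39937 bp), and the authors gave 1 whole-number count per feature, not normalised. Counts of host genes on both strands summed to 100.645% to 101.936% of the count of the whole chromosome, so that counting did not use strand. Reads of overlapping or antisense genes therefore could not be separated, and every alignment that touched a feature was counted for it. The host strain is known only from the reference, since the labels do not name it.

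The 2 runs of a replicate were summed to 1 library, which gave 15 libraries and n = 3 per time. The file of run 1 of 15 min replicate 3 ended early, at host position 4268343, and held no T7 features, so run 2 alone stood for that library. The labels call the replicates biological and do not say what separated them, so p-values measure the spread between these samples. No uninfected sample was among them. The files hold 4300 host protein-coding genes, of which 4296 had at least 1 count, and 240 pseudogenes, which were not used. A gene symbol could be given to 1262 of them. For 158 it came from the gene's own attribute, for 879 from a symbol inside the product name, for 222 from a product name matched to a fixed table and for 3 from another symbol in the files. Other genes are named by the locus tag of the files and their annotated product. Of the 60 T7 genes in the files 56 were used. Genes 0.6B, 4B, 5.5-5.7 and 10B, which repeat the sequence of another gene, were left out. Of the T7 genes 28 overlap another gene, and 38 of the tested host genes overlap another gene by at least 10%, so that their counts are partly shared. Ribosomal RNA (22 genes) and transfer RNA (85 genes) were counted apart from protein-coding genes. Transfer RNA is short, so that its counts may depend on how fragments were selected by size, which was not tested.

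The share of T7 counts was taken over the protein-coding counts of phage and host, and class shares over counts per kb of T7 genes. Both were set against time by permutation tests (two-sided, 100000 resamples) of Pearson's r and Spearman's rho, and later times against 5 min by exact permutation tests. T7 genes were tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) on all 15 libraries with time as the factor. Library sizes were total T7 counts with no further factors, so that a log2 fold change is the change of a gene's part of all T7 counts. Shares of a gene are per kb, and both scales can differ in sign. Host genes were tested in the same way, with TMM factors over the protein-coding genes kept by filterByExpr (2117 genes). A host fold change is thus relative to the typical host gene and not to total RNA. The comparisons were 10 against 5, 15 against 10, 20 against 15, 25 against 20 and 25 against 5 min. P-values were adjusted by the Benjamini-Hochberg method over the genes of a test, and genes with an adjusted p under 0.05 are said to have passed. Standard errors were derived from the log2 fold change and its F statistic and are approximate. They, and any interval or limit given, cover the fitted or counting error, and PCR reads without molecular identifiers are not independent molecules.

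Host gene lists (22, with 468 entries of which 348 matched a gene) were tested at 10 and at 25 against 5 min with limma's camera and a preset correlation of 0.01, and lists with at least 3 tested members entered. They were ribosomal proteins, translation factors, RNA polymerase and transcription factors, RNA degradation, the TCA cycle, glycolysis, ATP synthase, amino acid biosynthesis operons, nucleotide biosynthesis, iron acquisition, outer membrane proteins and lipopolysaccharide core biosynthesis. The others were flagella and chemotaxis, colanic acid and Rcs, cryptic prophages, toxin-antitoxin genes and the heat shock, cold shock, phage shock, SOS, envelope stress and general stress responses. With an estimated correlation, camera called 0 of 20 lists at 10 against 5 min (2 at an unadjusted p under 0.05, lowest adjusted p = 0.135) and 1 at 25 against 5 min (3 at an unadjusted p under 0.05). fry, which tests whether the genes of a list move on balance one way without comparing them with other genes, called 18 lists in each. Steps between neighbouring T7 genes were log2 ratios of counts per kb with a pseudocount of 0.5, over 50 pairs. The median over pairs with a promoter (13), an RNase III site (9) or a terminator (2) of the textbook T7 map was compared with that over the 32 pairs with none, by permuting the labels of pairs 100000 times (two-sided). The pair of gene 19 and the rightmost T7 gene, with the promoter phiOR between them, was counted among the 32. So were the pair of genes 4A and 4.2, with the T7 promoter phi4c inside gene 4A, and the pair of genes 0.5 and 0.7, with the E. coli B promoter inside gene 0.5. For the RNase III sites and terminators, groups of fewer than 10 pairs, the p given is exact, from all choices of pairs, and this choice was made after the data had been seen. Their alternatives used the resamples. The runs were compared by a chi-square test over genes with a summed count of at least 20 and expected counts of at least 5.

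Named T7 genes were the 5 with the highest counts per kb at each time, and up to 10 that rose and 10 that fell most in a comparison among genes that passed and whose replicates did not overlap. Genes 0.3, 0.7, 1, 2, 2.5, 3.5, 5, 6, 10A, 17 and 19 were always included. Named host genes for 10 and 25 against 5 min were the 12 that rose and the 12 that fell most among genes that passed, with replicates that did not overlap and at least 10 counts in each library of the higher time. For the other comparisons the first 4 each way were taken. From each list up to 4 members that passed, with the largest change, were added (2 at 10 against 5 min), and rne, rnc, rpoC, trxA, recB, dgt, udk and cmk always. The tests, the lists, this rule and most alternatives were chosen before the data were examined. The alternatives were other scalings (TMM over T7 genes, host totals alone, the total of phage and host counts, DESeq2 size factors), the Wald test of DESeq2, other filters on low counts, a fit on only the 2 times compared and the replicate number as a block. Others were each run alone, each library left out in turn, a further limit of 1 on the absolute log2 fold change, gene features in place of coding features, and thinning of each library to 173840 host counts. Alternatives added after the data had been seen left out host genes that overlap another, the gene with most counts or the 5 min libraries, or kept the T7 genes that repeat another's sequence.

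Tests were run on simulated counts with known changes first. Among 2117 simulated host genes for 25 against 5 min, 88% of those lowered by a log2 change of 2 and all of those raised by 2 were called, as were 72% of those lowered by 1 and 92% of those raised by 1, with 4.35% false calls. For 10 against 5 min at least 98% were called at each size, with 5.24% false calls. For 25 against 20 min 46% of those lowered by 1 and 72% of those raised by 1 were called. Of simulated steps with no shift 14 of 200 were called, and of those with a log2 shift of 2 all 20. A list moved by a log2 change of 1 was recovered among the 20 lists with no other called. The simulated genes were drawn independently, whereas the estimated correlation within lists of the data reached 0.35 at 25 against 5 min (RNA polymerase and transcription factors). The simulation thus cannot show how often lists of correlated genes are called falsely. R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 was used, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. A test of gene order within 1 ribosomal protein region, made after the data had been seen, is not reported here. Codon usage and GC content were not analysed here, because no genome sequence was used.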

Results

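RNA was sequenced from Escherichia coli infected with wild-type bacteriophage T7 at 25 °C, in libraries taken 5, 10, 15, 20 and 25 min after infection. T7 is a lytic phage with a genome of 39937 bp that is read from left to right. Its early genes are transcribed by the host RNA polymerase and its later genes by the phage's own RNA polymerase, the product of gene 1. Each time was represented by 3 biological replicates, 15 libraries in all. Each library was the sum of 2 sequencing runs except 15 min replicate 3, for which only 1 complete run was at hand. The study concerned transcript degradation and codon usage as means of gene regulation by the phage. Codon usage was not analysed here, because no genome sequence was used. No uninfected culture was among the samples, so 5 min served as the reference. The libraries held 40229038 to 87719937 alignments. Ribosomal RNA took 87.6% to 95.5% of the counts of all annotated genes, in which an alignment that touches more than 1 gene counts for each. Counts on host protein-coding genes fell from 3036884 to 5713229 per library at 5 min to 674825 to 1159023 at 10 min. They were 226094 to 449673 at 15 min, 206853 to 322577 at 20 min and 173840 to 248959 at 25 min. At 5 min 3378 to 3703 host genes had at least 10 counts, against 1227 to 1520 at 25 min. Counts on T7 genes were 631223 to 1082556 per library at 5 min, 3939804 to 6930204 at 10 min and 2437903 to 3687622 at 25 min.

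T7 transcripts took over the protein-coding counts between 5 and 10 min. Their share was 16.1% ± 1.1 (SD, n = 3) at 5 min and 85.2% ± 0.577 at 10 min. It was 89.96% ± 0.505 at 15 min, 92.9% ± 0.258 at 20 min and 93.6% ± 0.218 at 25 min. At each later time all 3 replicates lay above all 3 at 5 min, with a two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries allow. Over the 15 libraries the share rose with time with Pearson r = 0.770 and Spearman rho = 0.982. Each had a permutation p = 1e-05, the smallest that 100000 resamples can give. The 6 libraries at 5 and 25 min lie equally far from the median time, and leaving out any 2 of them gave r from 0.647 to 0.790. Among the counts of all annotated genes, ribosomal RNA included, the T7 share was highest at 10 min. On that scale it was 1.08% ± 0.123 at 5 min, 9.34% ± 0.968 at 10 min, 5.91% ± 0.552 at 15 min, 5.20% ± 0.25 at 20 min and 4.38% ± 0.389 at 25 min, and its r with time was 0.130 (permutation p = 0.645). Host protein-coding counts fell on that scale from 5.66% ± 0.799 at 5 min to 1.62% ± 0.135 at 10 min and 0.30% ± 0.0240 at 25 min, with an exact permutation p = 0.1 for each later time against 5 min.

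**Figure D1:**
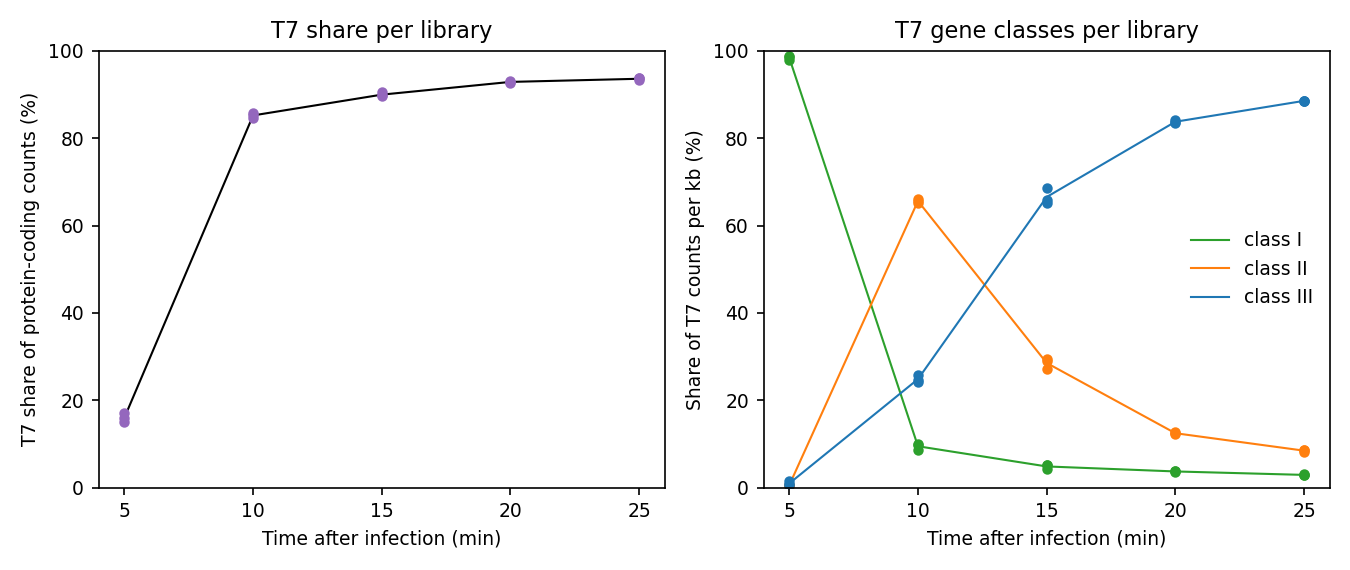
Each point is a library (n = 3 per time) and the lines join the means, with the T7 share of protein-coding counts (left, %) and the shares of the 3 T7 gene classes in T7 counts per kb (right, %) against minutes after infection. The T7 share rises from 16.1% to 93.6% and class III ends at 88.5%.

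The 3 temporal classes of T7 genes followed each other. Class I, genes 0.3 to 1.3 at the left end of the genome, holds the early genes for host takeover and gene 1. It made up 98.4% ± 0.528 of T7 counts per kb (SD, n = 3) at 5 min, 9.51% ± 0.705 at 10 min and 2.96% ± 0.132 at 25 min. Class II, genes 1.4 to 6.3, holds the DNA replication genes. Its share went from 0.601% ± 0.0939 at 5 min to 65.6% ± 0.436 at 10 min, then down to 28.6% ± 1.2 at 15 min, 12.5% ± 0.276 at 20 min and 8.50% ± 0.172 at 25 min. Class III, from gene 6.5 to the right end, holds the virion, DNA packaging and lysis genes. Its share went from 1.01% ± 0.436 at 5 min to 24.9% ± 0.756 at 10 min, 66.5% ± 1.72 at 15 min, 83.8% ± 0.262 at 20 min and 88.5% ± 0.0937 at 25 min. For each class the 3 libraries at 25 min lay apart from those at 5 min, with an exact permutation p = 0.1, the smallest possible. With time over the 15 libraries, class I had r = -0.745 and rho = -0.982, and class III had r = 0.964 and rho = 0.982. Each had a permutation p = 1e-05, and 1.5e-05 after adjustment over the 3 classes. Class II, which peaked at 10 min, had r = -0.228 (permutation p = 0.409, also after adjustment) and a rho of 0 (permutation p = 1). Without the 5 min libraries, a choice made after the data had been seen, its r was -0.929. Without 2 of the 6 libraries at the earliest and latest times, r ranged from -0.768 to -0.600 for class I, from -0.574 to -0.111 for class II and from 0.948 to 0.972 for class III.

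Between 5 and 10 min the T7 transcripts changed over from the left end to the middle of the genome. Gene 0.3 (positions 925 to 1278 of T7), whose product inhibits host restriction enzymes, fell from 28.4% ± 0.466 to 0.576% ± 0.0374 of T7 counts per kb (SD, n = 3). The log2 change in its part of all T7 counts was -6.15 (SE 0.15, adjusted p = 8.2e-16). Gene 0.7 (2021 to 3100), the protein kinase, changed by -6.85 (SE 0.15) from 7.23% ± 0.611 to 0.0904% ± 0.00661. The neighbouring genes 0.4, 0.5 and 0.6A changed by -5.90 (SE 0.17), -7.71 (SE 0.15) and -7.69 (SE 0.15). Gene 1 (3171 to 5822), the T7 RNA polymerase, changed by -2.42 (SE 0.13) from 1.35% ± 0.256 to 0.364% ± 0.0242. Scaled to the total of phage and host counts its change was 0.00 (adjusted p = 0.983). The replication genes rose. Gene 4A (primase and helicase, in which gene 4.1 lies) rose by 6.89 (SE 0.18), gene 6 (exonuclease) by 6.46 (SE 0.38) and gene 5 (DNA polymerase) by 6.23 (SE 0.25). Gene 2.5 (binding of single-stranded DNA) rose by 6.03 (SE 0.16), gene 2 (inhibitor of the host RNA polymerase) by 5.77 (SE 0.17) and gene 3.5 (lysozyme) by 5.67 (SE 0.27). The largest rise was in gene 4.5 (13584 to 13853), by 7.37 (SE 0.24). Gene 4.3 reached 8.67% ± 0.303 of T7 counts per kb at 10 min, the highest of the 56 genes at that time. The late genes 10A (major capsid protein) and 17 (tail fibre) changed by 3.83 (SE 0.24) and 3.32 (SE 0.21), which turned to -0.70 and -1.23 with DESeq2 size factors and to -0.97 and -1.50 with TMM factors over T7 genes. Of the 56 T7 genes tested with edgeR, 48 rose and 7 fell. With DESeq2 size factors 28 rose and 23 fell, and with TMM factors 22 rose and 24 fell. Both of these scalings assume that most genes do not change.

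From 10 to 15 min the balance moved on to the right part of the genome. Gene 10A (22967 to 24004) rose from 2.14% ± 0.123 to 6.60% ± 0.573 of T7 counts per kb (SD, n = 3), a log2 change of 1.22 (SE 0.21, adjusted p = 9.6e-05). Gene 17 (34624 to 36285) rose by 1.53 (SE 0.20). The tail protein genes 11 and 12 rose by 1.65 (SE 0.21) and 1.74 (SE 0.20), and gene 16 (internal virion protein) by 1.62 (SE 0.20). Gene 17.5 (lysis protein) rose by 1.49 (SE 0.34) and gene 18 (DNA maturation protein) by 1.66 (SE 0.30). The rightmost gene of the T7 map (39389 to 39538) rose most, by 1.98 (SE 0.31). Gene 4.3 fell from 8.67% ± 0.303 to 1.19% ± 0.171, a log2 change of -3.27 (SE 0.14, adjusted p = 5.6e-12). Genes 4.5 and 4A changed by -3.11 (SE 0.19) and -2.93 (SE 0.15), and genes 2 and 2.5 by -2.21 (SE 0.14) and -1.82 (SE 0.13). Gene 1 changed by -1.30 (SE 0.13) and gene 5 by -0.98 (SE 0.20) on the log2 scale. Of the 56 genes 24 rose and 30 fell, and with DESeq2 size factors 22 rose and 31 fell.

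From 15 to 20 min and from 20 to 25 min the T7 genes that passed the edgeR test were mostly genes of classes I and II that fell within the T7 counts. From 15 to 20 min gene 4A changed by -2.27 (SE 0.14) on the log2 scale (n = 3), gene 4.5 by -2.33 (SE 0.19), gene 4.3 by -2.26 (SE 0.13) and gene 2 by -2.14 (SE 0.14). Gene 9 (scaffolding protein) was the class III gene that fell, with -0.62 (SE 0.25, adjusted p = 0.0408), and was named after its value was seen. The gene that rose was the rightmost, from 8.12% ± 0.868 to 17.5% ± 0.912 of T7 counts per kb (SD, n = 3), a log2 change of 1.06 (SE 0.30, adjusted p = 0.00579). From 20 to 25 min gene 4.7 changed by -0.74 (SE 0.11, adjusted p = 2.8e-04), gene 1 by -0.74 (SE 0.12), gene 5 by -0.68 (SE 0.20) and gene 2 by -0.62 (SE 0.13). With DESeq2 size factors these values became -0.11, -0.11, -0.06 and 0.01 and no longer passed. Gene 10A did not pass in either step, at 0.11 (SE 0.21, adjusted p = 0.679) and 0.16 (SE 0.21, adjusted p = 0.595), but rose in both with DESeq2 size factors, by 0.81 and 0.79. From 15 to 20 min 1 gene rose and 30 fell. With DESeq2 size factors 26 rose and 20 fell, and with TMM factors 23 rose and 25 fell. From 20 to 25 min all 27 genes that passed fell, whereas all 22 that passed with DESeq2 size factors rose, and with TMM factors 9 rose and 12 fell. Fitted on the 20 and 25 min libraries alone, 11 rose and 44 fell.

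Set against 5 min, the T7 transcripts at 25 min were those of the right end of the genome. Gene 10A made up 8.24% ± 0.357 of T7 counts per kb at 25 min against 0.104% ± 0.0450 at 5 min (SD, n = 3), a log2 change of 5.31 (SE 0.26, adjusted p = 4.1e-12). Gene 17 made up 4.81% ± 0.0778 after a change of 5.28 (SE 0.23). The rightmost gene (39389 to 39538) reached 21% ± 1.4, the highest of the 56 genes at 25 min, after a change of 6.81 (SE 0.39). Its length of 150 bp raises its counts per kb, since every alignment that touches a gene was counted. The T7 promoter position phiOR (39229) lies between gene 19 and this gene. Gene 19 (DNA maturation protein, in which 19.2 and 19.3 lie), gene 13 (internal virion protein) and gene 6.5 changed by 5.52 (SE 0.28), 5.56 (SE 0.27) and 5.56 (SE 0.26). Gene 0.7 changed by -8.09 (SE 0.16, adjusted p = 6.4e-17), gene 0.5 by -8.23 (SE 0.16) and gene 0.3 by -6.90 (SE 0.16). Gene 1 changed by -5.24 (SE 0.15), from 1.35% ± 0.256 to 0.0706% ± 0.00217. Genes 2 and 2.5 were higher at 25 than at 5 min by 0.80 (SE 0.15) and 2.14 (SE 0.13) in their part of all T7 counts, but lower with DESeq2 size factors, at -2.83 and -1.45, and with TMM factors, at -3.48 and -2.10. Of the 56 genes 47 rose and 9 fell. With DESeq2 size factors 30 rose and 23 fell, and with TMM factors 23 rose and 26 fell.

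**Figure D2:**
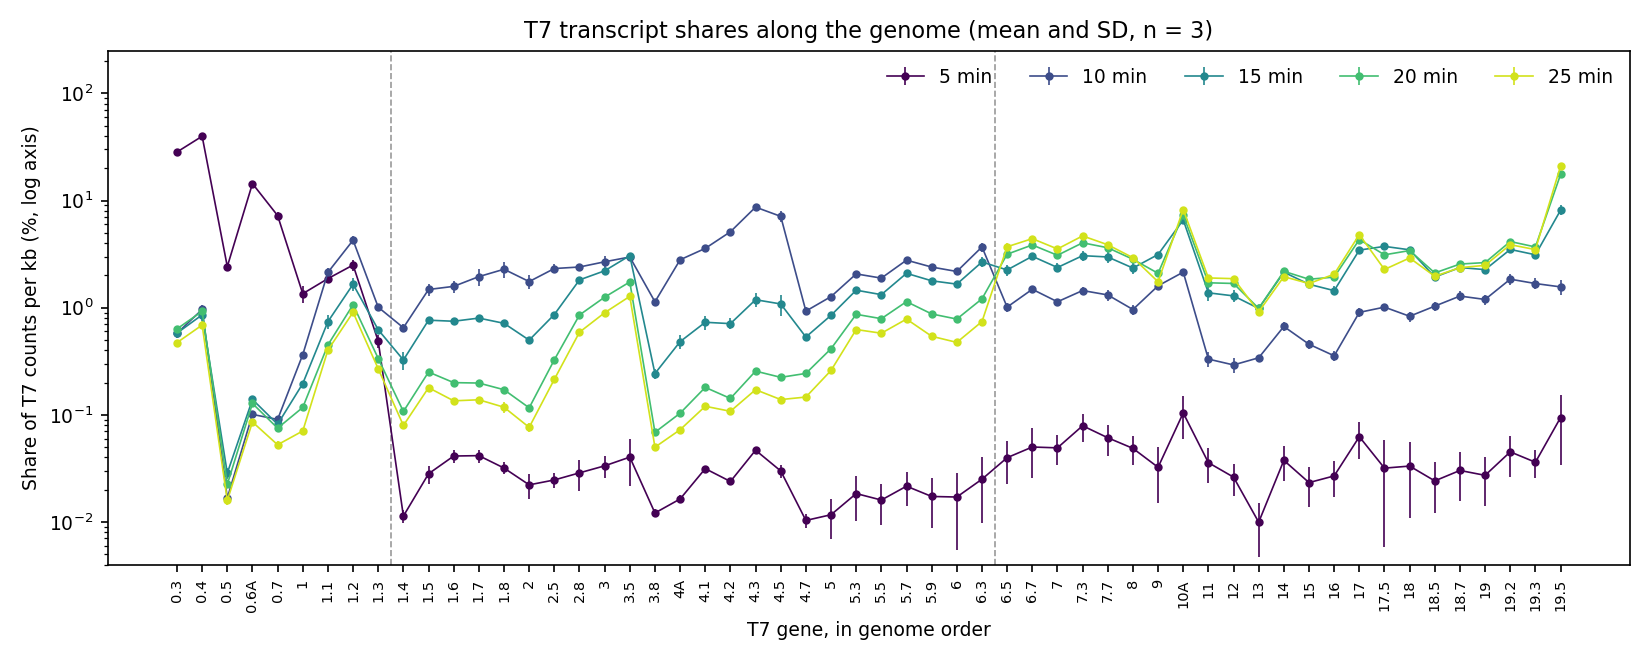
Share of T7 counts per kb (%, log axis) for the 56 T7 genes in genome order, as mean and SD of 3 replicates at each time, with dashed lines between the classes. At 5 min the highest values are at the left end, at 10 min gene 4.3 is highest (8.67%) and at 25 min the rightmost gene (21%).

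Steps in counts per kb between neighbouring T7 genes were set against the elements of the genome map, since the study asked how transcripts are processed and degraded. RNase III is the host enzyme that cleaves T7 transcripts. The median step over the 9 neighbouring pairs with a site for it was lower than over the 32 pairs with no element. Each step was taken as the gene after over the gene before. The median log2 step differed by -1.72 ± 0.20 at 5 min and -1.57 ± 0.11 at 10 min (SD over the 3 replicates). It differed by -1.10 ± 0.07 at 15 min, -1.0 ± 0.07 at 20 min and -0.92 ± 0.11 at 25 min, with adjusted p from 0.00126 to 0.0153 in an exact permutation test, over the 15 step tests. Across the 2 terminators, TE after gene 1.3 and Tphi after gene 10A, the difference was -3.64 ± 0.07 at 5 min and between -1.86 and -2.29 later. The exact permutation p was 0.00178 (adjusted p = 0.00382) at each time, the smallest that 2 pairs can give against 32. The annotation names TE a terminator of E. coli transcription and Tphi one of T7 transcription, so the pooled difference joins 2 unlike elements. The terminators differed in course, since the step across TE was -5.41 at 5 min and -0.64 at 10 min. That across Tphi was -1.52 and -2.71. Across the 13 pairs with a T7 RNA polymerase promoter, the gene after it stood above the gene before it by 0.17 to 0.54 more than in pairs with no element. The adjusted permutation p ran from 0.197 to 0.773, so that no such step passed. The promoter position phiOR (39229) lies between gene 19 and the rightmost gene, but that pair was counted among the 32. Its step was 2.73 at 20 min and 3.08 at 25 min. A test with it as a promoter pair was not run. The T7 promoter position phi4c (12671) lies inside gene 4A, ahead of the start of gene 4.2. That pair, with steps of 0.46 to 0.87, was also among the 32. The E. coli B promoter (1514) lies inside gene 0.5, in another of these pairs. No test was run with these pairs moved. In the promoter pairs without an RNase III site the difference was 0.79 at 5 min and 0.86 at 20 min, and passed at these 2 times. Pairs along a genome are not independent replicates, and several RNase III sites lie beside a promoter. In the RNase III pairs without a promoter the difference was 0.13 at 10 min, -1.0 at 20 min and -0.92 at 25 min, and no longer passed at these times. Without pairs whose genes overlap it was -0.98 at 20 min and -0.91 at 25 min, and no longer passed.

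Host transcripts at 10 min were compared with those at 5 min relative to the typical host gene, because the host share of all counts fell. rpoC (positions 4062566 to 4066789 of the host chromosome) and rpoB, which encode the large subunits of the host RNA polymerase, rose. rpoC went from 1192 ± 146 to 5695 ± 351 CPM of TMM-normalised host counts (SD, n = 3), a log2 change of 2.26 (SE 0.10, adjusted p = 1.1e-15), and rpoB changed by 2.03 (SE 0.12). aceF, a subunit of pyruvate dehydrogenase, rose by 2.12 (SE 0.11), and the isocitrate lyase gene SR36_RS20235, of the glyoxylate bypass, by 2.01 (SE 0.22). The glycine dehydrogenase gene SR36_RS14100 rose by 1.89 (SE 0.11) and the sulfate-binding transport gene SR36_RS11880 by 2.38 (SE 0.45). The thymidine kinase gene SR36_RS06270 (1250483 to 1251100) fell from 197 ± 15.3 to 33.8 ± 4.51 CPM, a log2 change of -2.55 (SE 0.14, adjusted p = 1.8e-14). cspE (cold-shock protein family) changed by -2.27 (SE 0.15), ychF (an ATPase) by -2.24 (SE 0.11) and stpA (a nucleoid protein) by -2.24 (SE 0.15). efp (elongation factor P) changed by -2.20 (SE 0.14) and plaP (a putrescine importer) by -2.10 (SE 0.12). Of the host partners of T7, rnc (RNase III) changed by -1.53 (SE 0.12), trxA (thioredoxin, a subunit of the T7 DNA polymerase) by -1.02 (SE 0.11) and udk (uridine kinase) by -2.12 (SE 0.19). rne (RNase E) stood at -0.04 (SE 0.10, adjusted p = 0.715) and dgt (dGTP triphosphohydrolase, the target of gene 1.2) at -0.19 (SE 0.15, adjusted p = 0.283), and neither passed. recB (a subunit of the RecBCD nuclease) and cmk (cytidylate kinase) rose by 0.54 (SE 0.15) and 0.45 (SE 0.12), but stood at 0.09 and -0.01 when scaled to host totals alone, where neither passed. On that scale rne and dgt passed, at -0.51 and -0.64. Of 2117 host genes tested with edgeR, 715 rose and 680 fell. With host totals alone 357 rose and 1133 fell, and with the total of phage and host counts 1 rose and 2113 fell. The median log2 change of the tested host genes from 5 to 10 min was 0.03 with the TMM scaling used here, -0.43 with host totals alone and -2.93 with the total of phage and host counts. From 5 to 25 min it was 0.02, -0.26 and -3.96. On that last scale every host gene named here as having risen against 5 min stood below 0, with 3 exceptions from 5 to 25 min that did not pass. These were glycogen phosphorylase (0.37), the efflux gene SR36_RS16070 (0.15) and isocitrate lyase (0.02).

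Of the 22 gene lists drawn up before the data were examined, 20 had enough tested members, and at 10 min 3 of them stood above the other host genes against 5 min. Among 53 ribosomal protein genes 39 rose, 10 fell and 4 did not pass (camera adjusted p = 8.7e-08, and adjusted p = 0.313 with an estimated correlation), or 31 and 14 with host totals alone. Among those that fell, rpsT (protein S20) changed by -2.06 (SE 0.12) and rpsU (protein S21) by -1.89 (SE 0.11). Of 14 genes of the TCA cycle, the central oxidative pathway, 13 rose (camera adjusted p = 1.2e-04, and adjusted p = 0.135 with an estimated correlation), or 10 with 1 that fell under host totals alone. Among them sucB (2-oxoglutarate dehydrogenase) rose by 1.86 (SE 0.14) and acnB (aconitase) by 1.74 (SE 0.12). Of 9 ATP synthase genes 6 rose (camera adjusted p = 0.0496, and adjusted p = 0.350 with an estimated correlation), whereas 4 rose and 3 fell with host totals alone. Among them atpC rose by 1.93 (SE 0.11) and atpD by 1.85 (SE 0.12). The ATP synthase call ended without 5 min replicate 1 (adjusted p = 0.0524), without 10 min replicate 2 (0.0501), without 10 min replicate 3 (0.0623) and with host totals alone (0.105). Among lists that did not pass as a whole, 11 of 19 amino acid biosynthesis genes rose and 2 fell (adjusted p = 0.0598), or 9 and 4 with host totals alone, with ilvC (branched-chain amino acids) at 1.78 (SE 0.12). All 6 phage shock genes rose (adjusted p = 0.0973), with pspB at 0.70 (SE 0.13), but with host totals alone the list's median log2 change went from 0.60 to 0.14 and edgeR called 0 of the 6, also at an unadjusted p under 0.05 (pspB 0.23, adjusted p = 0.101). Of 7 outer membrane protein genes 3 rose and 3 fell (adjusted p = 0.629), or 3 and 4 with host totals alone, with lamB (maltoporin) at 1.78 (SE 0.12) and tolC at -1.42 (SE 0.13). Of 11 translation factor genes 7 rose and 3 fell (adjusted p = 0.106), or 5 and 4 with host totals alone, with fusA (elongation factor G) at 1.47 (SE 0.09). Under host totals alone the median log2 change turned from 0.30 to -0.17 for ATP synthase and from 0.17 to -0.29 for outer membrane proteins. In all 20 lists the counts adjusted over the list alone equalled those adjusted over all genes tested. With the total of phage and host counts all tested members of every list fell, at 10 and at 25 min. Of the 10 ways to split the 6 libraries into 3 and 3, another gave up to 6 lists past the camera threshold, against 3 for the real times. The other splits mix both times and keep part of their difference, so they cannot show how many lists chance would give. Median, mean and test differed in sign for the cold shock list (median log2 change 0.49, mean 0.05, camera up, fry down). They also did for glycolysis (0.05, -0.24, down) and for RNA polymerase and transcription factors (-0.09, 0.28, up).

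From 10 to 15 min fewer host genes passed than from 5 to 10 min. rpoC rose further, by 0.92 (SE 0.10, adjusted p = 9.3e-08) to 10763 ± 1357 CPM of TMM-normalised host counts (SD, n = 3). fecI, the sigma factor gene of iron citrate transport, rose by 1.44 (SE 0.34). It did not pass in run 1 alone (1.3, adjusted p = 0.0746) or after thinning all libraries to the smallest host total (1.54, adjusted p = 0.0889). The gene SR36_RS16855 (3379541 to 3381934), annotated as glycogen phosphorylase and named here by that annotation alone, rose by 1.90 (SE 0.21). Its counts were 0.0525% ± 0.0204 of ribosomal RNA counts at 10 min and 0.0715% ± 0.00232 at 15 min. The 2 runs of 10 min replicate 2 held 831 and 16532 counts of it, where other genes had a ratio of 1.44 between these runs, and its change was 2.18 in run 1 alone and 1.43 in run 2 alone. The lipopolysaccharide galactosyltransferase gene SR36_RS17995 (3636540 to 3637565) fell by 1.61 (SE 0.29) on the log2 scale. The largest fitted change, 5.34 (SE 0.90) for the glyoxylate reductase gene SR36_RS17590, rested on 15 min replicate 2. That library had 3330 counts, 3320 of them in 1 of its 2 runs, against 25 and 43 in the other replicates, and without it the change was 0.33 (adjusted p = 0.391). In all 126 rose and 177 fell by edgeR's test. With host totals alone 70 rose and 241 fell, and with the total of phage and host counts 9 rose and 1198 fell.

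After 15 min most host genes that changed fell, and many of these encode ribosomal proteins, namely 18 of the 40 that fell from 15 to 20 min and 31 of the 39 that fell from 20 to 25 min. From 15 to 20 min rplD (protein L4, positions 3282016 to 3282621) changed by -1.32 (SE 0.14, adjusted p = 4.9e-07), to 6184 ± 261 CPM of TMM-normalised host counts (SD, n = 3). rplW (protein L23) changed by -0.96 (SE 0.10) and ibpA (a small heat shock protein) by -1.24 (SE 0.22). From 20 to 25 min rplD changed by -1.15 (SE 0.14), rplW by -1.15 (SE 0.10), rplB (protein L2) by -1.11 (SE 0.10) and rplC (protein L3) by -1.08 (SE 0.10). Risers were few. From 15 to 20 min they were lamB, at 0.51 (SE 0.12, adjusted p = 0.0193), and the phosphotrehalase gene SR36_RS21425, at 0.54 (SE 0.13, adjusted p = 0.0253). From 20 to 25 min they were the phosphodiesterase gene SR36_RS21315, at 0.89 (SE 0.23, adjusted p = 0.0379), and the oxoacyl-ACP synthase gene SR36_RS11450, at 0.57 (SE 0.15, adjusted p = 0.0379). Each of these 4 calls ended when single libraries were left out. lamB did not pass without 15 min replicate 1 (adjusted p = 0.106), 15 min replicate 2 (0.116), 20 min replicate 1 (0.0997) or 20 min replicate 2 (0.0572), and SR36_RS21425 did not without 15 min replicate 2 (adjusted p = 0.0656), 15 min replicate 3 (0.0953), 20 min replicate 2 (0.205) or 20 min replicate 3 (0.0640). SR36_RS21315 did not pass without 20 min replicate 1 (adjusted p = 0.142), 20 min replicate 2 (0.202), 25 min replicate 1 (0.154), 25 min replicate 2 (0.123) or 25 min replicate 3 (0.0603). SR36_RS11450 did not without 20 min replicate 1 (adjusted p = 0.167), 20 min replicate 2 (0.0732), 20 min replicate 3 (0.119), 25 min replicate 1 (0.0954) or 25 min replicate 3 (0.237). From 15 to 20 min 2 rose and 40 fell, and 19 rose and 20 fell with host totals alone. Without 15 min replicate 1, and likewise without 15 min replicate 2, 26 genes passed. From 20 to 25 min 2 rose and 39 fell, and 4 rose and 20 fell with host totals alone. Without 20 min replicate 1, 23 passed, and without 25 min replicate 3, 24 passed.

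From 5 to 25 min the host gene that rose most against the typical host gene was that of glycogen phosphorylase, and the one that fell most was iraM. Glycogen phosphorylase (SR36_RS16855) went from 9410.0 ± 1348 to 194797 ± 29644 CPM of TMM-normalised host counts (SD, n = 3), a log2 change of 4.37 (SE 0.23, adjusted p = 1.7e-15). Its counts were 0.0721% ± 0.00496 of ribosomal RNA counts at 5 min and 0.0634% ± 0.00241 at 25 min, so that it did not rise on that scale. The isocitrate lyase gene SR36_RS20235 (4094159 to 4095463) rose by 4.01 (SE 0.24, adjusted p = 1.7e-14). The neighbouring isocitrate dehydrogenase kinase and phosphatase gene SR36_RS20240, which directs carbon into the same bypass, rose by 3.64 (SE 0.32). The protein lysine acetyltransferase gene SR36_RS12695 rose by 3.78 (SE 0.15), lamB by 3.08 (SE 0.13) and the glycine dehydrogenase gene SR36_RS14100 by 3.07 (SE 0.13). The efflux pump gene SR36_RS16070 (3244185 to 3245342) rose from 4.22 ± 1.80 to 73.3 ± 22.8 CPM, a log2 change of 4.12 (SE 0.36), and fecI by 2.83 (SE 0.29). iraM (1169008 to 1169331), an antiadapter that stabilises the sigma factor RpoS, fell from 945 ± 76.9 to 127 ± 20.9 CPM, a log2 change of -2.91 (SE 0.14, adjusted p = 3.3e-16). rpsT changed by -2.88 (SE 0.13), efp by -2.80 (SE 0.15), cspE by -2.76 (SE 0.25), rpsU by -2.72 (SE 0.12) and stpA by -2.52 (SE 0.22). Of the partners of T7, rnc changed by -1.63 (SE 0.18), trxA by -1.49 (SE 0.12), udk by -1.68 (SE 0.31) and recB by 1.28 (SE 0.21). rne, at 0.28 (SE 0.13, adjusted p = 0.0587), dgt, at -0.16 (SE 0.26, adjusted p = 0.612), and cmk, at -0.13 (SE 0.19, adjusted p = 0.575), did not pass. cmk passed without 25 min replicate 3 (-0.52, adjusted p = 0.0284). The small values of rne and cmk turned sign in other settings, rne to -0.00 with host totals alone and cmk to 0.31 after thinning. Of the 2117 genes tested, 623 rose and 632 fell. With host totals alone 460 rose and 805 fell, and with the total of phage and host counts all 2110 that passed fell. Host totals include glycogen phosphorylase, which made up 1.2% ± 0.185 of host counts at 5 min and 20.3% ± 2.41 at 25 min. Its larger share by itself lowers the other genes on the scale of host totals alone, also in the lists below. A fit on host totals without this gene was not made. Across the tested genes, which are not independent replicates, the log2 change had a Spearman rho of -0.482 with the level at 5 min. The filter on counts favours a negative rho, since a gene low at 5 min was tested only if its counts sufficed at later times.

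**Figure D3:**
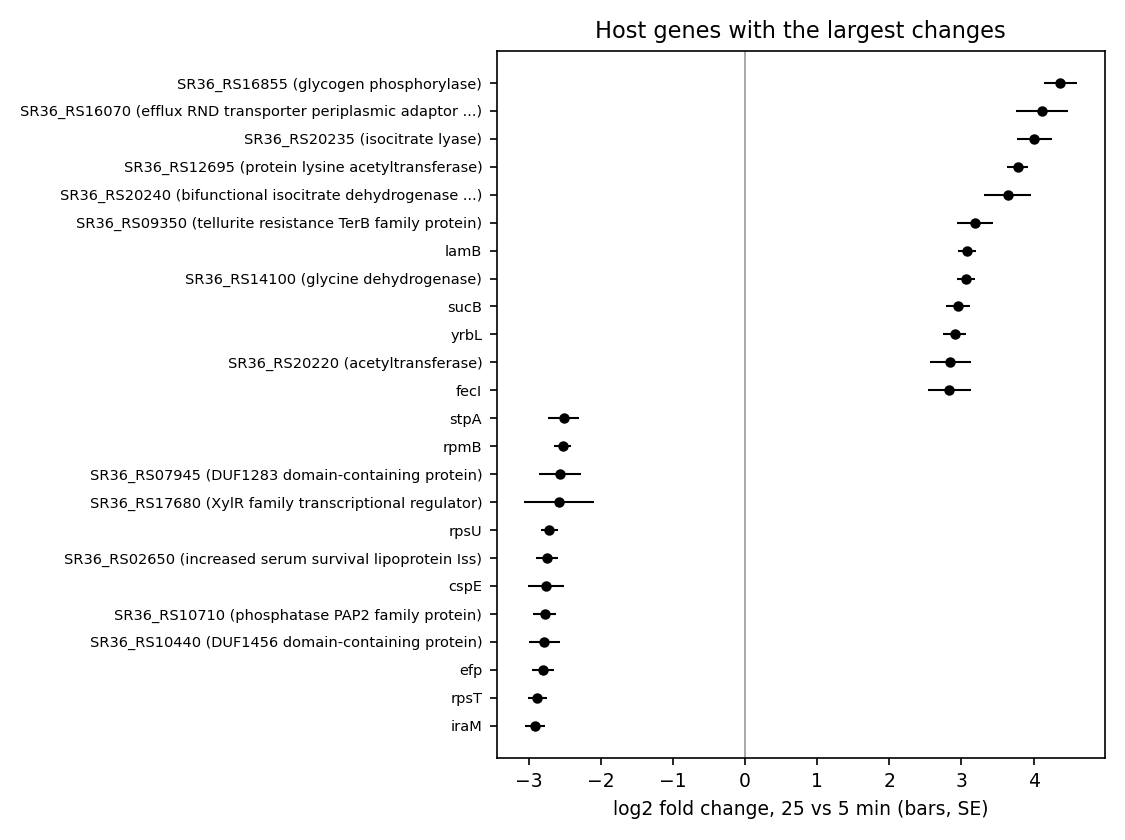
Log2 fold change (points) and SE (bars) from 5 to 25 min of the 12 host genes that rose and the 12 that fell most relative to the typical host gene. They run from -2.91 for iraM to 4.37 for glycogen phosphorylase, and scaled to the total of phage and host counts all but 3 of the risers lie below 0.

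Of the gene lists, 2 stood above the other host genes at 25 against 5 min. All 14 tested TCA cycle genes rose (camera adjusted p = 3.6e-07, and adjusted p = 0.0269 with an estimated correlation), 13 with host totals alone. Among them sucB rose by 2.95 (SE 0.17), acnB by 2.36 (SE 0.13) and sucC (succinyl-CoA synthetase) by 2.36 (SE 0.19). Of 19 amino acid biosynthesis genes 14 rose and 2 fell (camera adjusted p = 0.00213, and adjusted p = 0.0752 with an estimated correlation), or 12 and 2 with host totals alone. hisC (histidine) stood at 2.88 (SE 0.42), and ilvD and ilvC (branched-chain amino acids) at 2.63 (SE 0.23) and 2.44 (SE 0.12). The other lists did not pass as a whole, and their adjusted p is the camera value. Of 12 iron acquisition genes 8 rose and the other 4 did not pass (adjusted p = 0.0512). entE, entB and entF, for the siderophore enterobactin, rose by 3.24 (SE 0.43), 2.53 (SE 0.39) and 2.41 (SE 0.34). Of 15 envelope stress genes 9 rose and 3 fell (adjusted p = 0.176), or 6 and 4 with host totals alone. The periplasmic chaperone gene spy stood at 2.70 (SE 0.16), the periplasmic protease gene degP at 2.40 (SE 0.14) and cpxP at 2.20 (SE 0.13). All 6 phage shock genes rose (adjusted p = 0.137), 2 with host totals alone, pspC by 0.95 (SE 0.16) and pspB by 0.81 (SE 0.17). Of these, pspG did not pass without 25 min replicate 1 (0.78, adjusted p = 0.190) or replicate 3 (1.08, adjusted p = 0.0516), nor pspD without 25 min replicate 3 (0.56, adjusted p = 0.112). Of 13 SOS response genes 6 rose and 7 did not pass (adjusted p = 0.137), or 4 that rose and 1 that fell with host totals alone, with the toxin gene tisB at 1.93 (SE 0.13) and uvrA (DNA excision repair) at 1.89 (SE 0.20). Of 10 lipopolysaccharide core genes 2 rose and 5 fell (adjusted p = 0.537), or 1 and 5 with host totals alone, with rfaP at -1.50 (SE 0.23) and gmhB at -1.31 (SE 0.32).

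Other lists held genes that went both ways from 5 to 25 min. Of 53 ribosomal protein genes 23 rose and 23 fell (camera adjusted p = 0.808), or 22 and 29 with host totals alone, with rpmB (protein L28) at -2.52 (SE 0.12) and rpmE (protein L31) at -2.50 (SE 0.14). Of 11 genes for RNA polymerase and transcription factors 5 rose and 3 fell (adjusted p = 0.454), or 4 and 4 with host totals alone. rpoC rose by 2.82 (SE 0.11), rpoB by 1.74 (SE 0.12) and rpoA by 1.53 (SE 0.08), and the elongation factor gene greA stood at -1.78 (SE 0.21). Of 9 ATP synthase genes 4 rose and 2 fell (adjusted p = 0.137), or 4 and 3 with host totals alone, with atpD at 2.49 (SE 0.12) and atpG at 1.85 (SE 0.11). Of 17 heat shock genes 2 rose and 8 fell (adjusted p = 0.20), or 3 and 8 adjusted over the list alone and 1 and 9 with host totals alone. grpE stood at -2.18 (SE 0.13), ibpA at -2.19 (SE 0.19) and the chaperone gene clpB at 1.52 (SE 0.12). Of 14 RNA degradation genes 2 rose and 7 fell (adjusted p = 0.537), or 3 and 7 adjusted over the list alone and 1 and 7 with host totals alone, with rnr (RNase R) at 1.32 (SE 0.16) and rna (RNase I) at -1.51 (SE 0.23). All 9 glycolysis genes passed, 4 upward and 5 downward (adjusted p = 0.137), or 1 and 5 with host totals alone, with pykF (pyruvate kinase) at -1.75 (SE 0.11) and eno (enolase) at -1.02 (SE 0.09). Of 25 nucleotide biosynthesis genes 7 rose and 8 fell (adjusted p = 0.860), or 6 and 11 with host totals alone, with purH (purines) at 2.31 (SE 0.36) and ndk (nucleoside diphosphate kinase) at -1.94 (SE 0.15). Of 7 outer membrane protein genes 3 rose and 4 fell (adjusted p = 0.472), or 2 and 4 with host totals alone, with ompX at -2.14 (SE 0.09). Of 13 flagella and chemotaxis genes 6 rose and 4 fell (adjusted p = 0.629), or 6 and 5 with host totals alone, with flgE (hook protein) at 1.80 (SE 0.18) and flhD (the master regulator) at -1.77 (SE 0.39).

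Among the smaller lists at 25 against 5 min, 5 of 9 general stress genes rose and 2 fell (camera adjusted p = 0.472), or 3 and 3 with host totals alone, with poxB (pyruvate oxidase) at 2.68 (SE 0.41) and katE (catalase) at 2.39 (SE 0.44). Of 5 cold shock genes 4 rose and hns (a nucleoid protein) fell, at -2.18 (SE 0.12) (adjusted p = 0.860). With host totals alone edgeR called 0 that rose, also at an unadjusted p under 0.05, and 1 that fell. On that scale the larger share of glycogen phosphorylase at 25 min lowers the other genes. The values of rbfA, nusA and cspG there were 0.18, 0.17 and 0.16. Their calls also ended on leaving out single libraries. rbfA did not pass without 5 min replicate 1 (adjusted p = 0.0590), 5 min replicate 2 (0.0619), 25 min replicate 1 (0.189), 25 min replicate 2 (0.0957) or 25 min replicate 3 (0.0761), nusA without 25 min replicate 1 (adjusted p = 0.102) or cspG without 5 min replicate 2 (adjusted p = 0.0544) or 25 min replicate 1 (0.402). Of 11 translation factor genes 3 rose and 3 fell (adjusted p = 0.791), or 3 and 5 with host totals alone, with infC (initiation factor IF-3) at 0.71 (SE 0.09) and tsf (elongation factor Ts) at -1.34 (SE 0.10). Of 5 toxin and antitoxin genes 3 fell, or 4 adjusted over the list alone (adjusted p = 0.421). These were dinJ at -1.05 (SE 0.33), mazF at -0.90 (SE 0.32) and yafQ at -0.78 (SE 0.32). dinJ did not pass without 25 min replicate 1 (adjusted p = 0.0697), mazF without 25 min replicate 2 (adjusted p = 0.0968) or yafQ without 5 min replicate 1 (adjusted p = 0.0630), 5 min replicate 3 (0.0613), 25 min replicate 1 (0.158) or 25 min replicate 3 (0.297). The cryptic prophage list had 1 tested member, trkG (a potassium transporter gene), at -0.97 (SE 0.24, adjusted p = 0.00106). The colanic acid and Rcs list, with 15 genes in the files, had none with enough counts to be tested. Under host totals alone the median log2 change of a list turned from 0.15 to -0.13 for translation factors, from 0.19 to -0.09 for ATP synthase and from 0.01 to -0.28 for RNA polymerase and transcription factors. In the lists for which no counts adjusted over the list alone are given, these equalled those over all genes tested. Of the 10 ways to split the 6 libraries into 3 and 3, another gave up to 4 lists past the camera threshold, against 2 for the real times. The other splits mix both times and keep part of their difference, so they cannot show how many lists chance would give. Median, mean and test differed in sign for cold shock (median log2 change 0.45, mean -0.08, camera up, fry down) and for flagella and chemotaxis (-0.20, 0.16, up). They also did for translation factors (0.15, -0.33, down) and nucleotide biosynthesis (median -0.13, camera down, fry up).

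**Figure D4:**
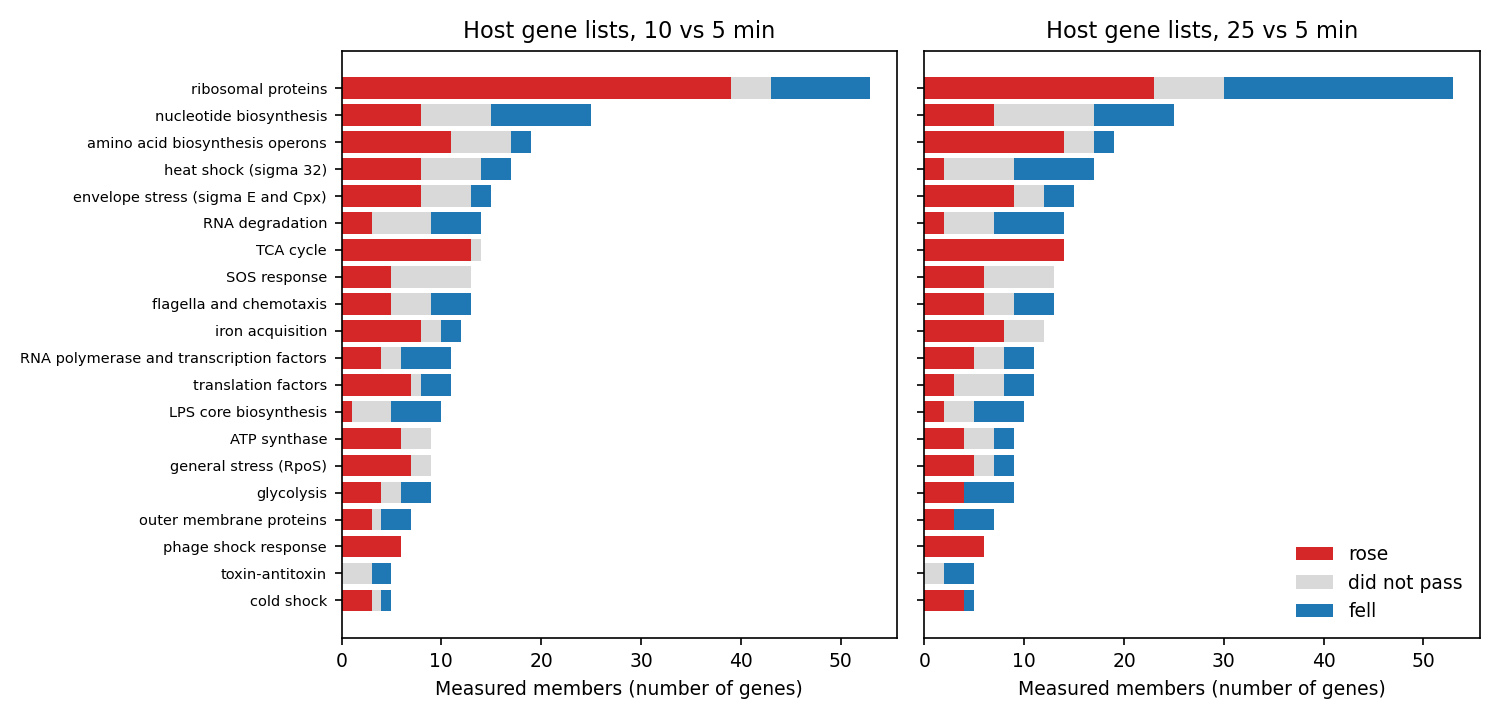
Number of tested genes of each list that rose, did not pass or fell against 5 min, at 10 min (left) and 25 min (right), by edgeR's test relative to the typical host gene. All 14 TCA cycle genes rose at 25 min, and of the 53 ribosomal protein genes 39 rose at 10 min against 23 at 25 min, whereas with the total of phage and host counts all members of every list fell.

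The 2 sequencing runs of a library differed less over genes than biological replicates of a time did at 5, 10, 15 and 25 min, judged by medians, but not at 20 min. In a chi-square comparison of counts over host and T7 genes, the statistic per degree of freedom was 1.1 to 11.3 between the runs (median 1.72, 15 pairs). The pair of 15 min replicate 3 (1.35) covered only the host genes in its incomplete run, which was used nowhere else. In the 14 libraries with 2 complete runs, 8 cases of a gene with at least 100 counts differed at least 3 times between runs from the ratio over other genes, a comparison chosen after the data had been seen. Between biological replicates it was 2.81 to 34.95 (median 10.4, 15 pairs). At 20 min the values were 1.1 to 10.8 between runs (median 5.38) and 2.81 to 6.5 between biological replicates (median 4.56). Glycogen phosphorylase had 7854 and 18631 counts in the runs of 20 min replicate 1 and 21268 and 6832 in those of replicate 3. Other genes had a ratio of 1.44 between these runs. The comparison was not made without this gene, so the 20 min values may rest largely on it. At 10 min replicate 2 held 831 and 16532 of its counts, and replicate 3 held 15928 and 10 of SR36_RS14395. Runs of 1 replicate were summed and counted as 1 library, which gave n = 3 per time.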

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

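The tests of explanations reported here were chosen after the results had been seen.

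The glycogen phosphorylase gene (SR36_RS16855, positions 3379541 to 3381934) went from 1.2% ± 0.185 of host protein-coding counts at 5 min to 20.3% ± 2.41 at 25 min (SD, n = 3). The ratio of 25 to 5 min of its counts per ribosomal RNA count was 0.879, against 0.0431 for the median tested gene. The second highest ratio was 0.733, and 3 tested genes, this one included, had a ratio of at least 1/1.5. Single libraries ran from 0.0299% (10 min replicate 2) to 0.0779% (5 min replicate 2) of ribosomal RNA counts. The lowest were 10 min replicate 2 and 20 min replicate 1 (0.0374%). In both, and in 20 min replicate 3 (21268 and 6832 counts), the gene's ratio between the 2 runs was far from that of other genes (1.44). Runs of 1 library share its RNA, so a constant ratio to ribosomal RNA did not hold in these libraries. What made the runs differ is not known, so from counts alone reads that follow ribosomal RNA cannot be told apart from other sources. The 2 runs of 10 min replicate 2 held 831 and 16532 of its counts and those of 20 min replicate 1 held 7854 and 18631, yet a difference between runs as the whole cause is argued against, since the lower of the changes in each run alone was 4.28. A transcript shared with the neighbouring 4-alpha-glucanotransferase gene is argued against, since the log2 change of that gene was 1.53 (SE 0.12), lower by a difference of 2.84. A biological difference between the times, such as a slower decay of this transcript, stays open and was not tested.

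Host genes with low levels at 5 min had larger log2 changes from 5 to 25 min, with a Spearman rho of -0.482 across the tested genes, which are not independent replicates. The filter on counts favours a negative rho, since a gene low at 5 min was tested only if its counts sufficed at later times. The checks that follow used the same genes and cannot exclude this. The values argue against coding length (partial rho -0.482 given length, where length alone had a rho of 0.306) and against the lower host depth at 25 min (rho -0.473 after thinning to equal totals). They also argue against counting error shared by both measures, since the level in 5 min replicate 1 and the change against the other replicates had a rho of -0.468. A background of host genomic DNA cannot be told apart from a change of transcripts, since the rho was -0.450 after the 25 min counts per kb of the 430 genes lowest at 5 min (0.525 per kb) were subtracted from every tested gene but 0.0675 after 10 times that level, and how evenly such reads would spread is not known. GC content was not tested, and a slower decay of rare transcripts is an untested hypothesis that may be considered.

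Counts over the left-end A0 position of T7 (position 224), an E. coli promoter on the leftward strand, made up 0.0138% ± 0.00189 of T7 counts at 5 min, 0.00154% ± 0.000649 at 10 min and 0.105% ± 0.00845 at 25 min (SD, n = 3). The feature, with a mean of 3263 counts at 25 min, is listed because it lies outside the comparisons of the report. T7 genomic DNA in the libraries is argued against, since 19 of the 36 element positions had under 0.1 of the A0 counts at 25 min. Transcripts that run from the right end into the left end of joined genomes cannot be told apart from leftward transcription from A0, because counting did not use strand, although the ratio of A0 to phiOR counts rose from 0.00693 ± 0.00238 at 10 min to 0.352 ± 0.0215 at 25 min, or 50.8 times. No biological explanation was tested.

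Other features outside the comparisons are listed as values alone. Each had more than the 3 counts that a count of 0 allows in every 25 min library, a limit that says little at this depth, and there was no control sample. The T7 promoter position phiOL (position 405) had a mean of 1943 ± 555 counts at 25 min (SD, n = 3), and phiOR (position 39229) had 9222 ± 2208. The transfer-messenger RNA ssrA, which rescues stalled ribosomes, had 35908 ± 8046 counts at 25 min, and its counts per ribosomal RNA count were 20.4% of those at 5 min. The 6S RNA ssrS had 3316 ± 652 counts and 18.2%, and the RNase P RNA rnpB had 7369 ± 1698 counts and 32.2%. Transfer RNA had 1473 ± 376 counts and 2.14%, where host protein-coding genes as a whole had 5.15%. Groups of 3 libraries were too small for a test of single outlying samples.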

How the results depend on the processing

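These alternatives were chosen after seeing the data: host genes without those that overlap another by 10% or more, host genes without glycogen phosphorylase, T7 genes with the 4 that repeat another's sequence, T7 totals without the gene with most counts, and T7 shares and class shares without the 5 min libraries. The other alternatives were planned. Of 376 values of the main results under an alternative 332 kept their direction and side of the threshold or stayed within 1.5 times, 35 moved, 5 no longer passed, 3 newly passed and 1 changed sign. Of 4193 such values of named host genes 3861 kept both, of 2281 of named T7 genes 2100 did and of 55 of gene lists 46 did. Where a value changed, the cause was not tested, except where fewer libraries or counts entered or the threshold was stricter. With the total of phage and host counts 2114, 1207, 285 and 2110 host genes passed at 10 against 5, 15 against 10, 20 against 15 and 25 against 5 min. With an absolute log2 change of at least 1 also required, 505, 63, 7, 5 and 785 passed in the 5 comparisons, and edgeR left 29, 20 and 0 T7 genes at 15 against 10, 20 against 15 and 25 against 20 min (27 in the last without that requirement). Thinning left 690 host genes at 10 against 5 and 183 at 15 against 10 min, and run 1 alone 137 at 15 against 10 min. At 25 against 20 min 24 passed with host totals alone and 62 with the DESeq2 Wald test. Leaving out single libraries gave 26 to 46 at 20 against 15 and 23 to 37 at 25 against 20 min, where the counts that differed by over 1.5 times were 26 without 15 min replicate 1 (20 against 15 min), 26 without 15 min replicate 2 (20 against 15 min), 23 without 20 min replicate 1 (25 against 20 min) and 24 without 25 min replicate 3 (25 against 20 min). The DESeq2 Wald test called 47 T7 genes and TMM factors 48 at 20 against 15 min, and a fit on the 2 times alone 55 at 25 against 20 min. Without a filter 10 lists passed at 25 and 9 at 10 against 5 min, with camera's estimated correlation 1 and 0 (2 lists at 10 min had an unadjusted p under 0.05), and with fry 18 and 18. Counted over all genes with ribosomal RNA, the T7 share had an r of 0.130 with time and means of 1.08% at 5 and 4.38% at 25 min. Per kb the means were 22.5% and 93.3%, and 92.7% at 25 min without the T7 gene with most counts. Class II without the 5 min libraries had an r of -0.929. Promoter steps without an RNase III site passed at 5 min (0.79) and 20 min (0.86). RNase III steps without a promoter were 0.13 at 10 min, -1.0 at 20 min and -0.92 at 25 min, and without overlapping pairs -0.98 at 20 min and -0.91 at 25 min, none of which passed.

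With the replicate number as a block 55, 51, 31, 27 and 56 T7 genes and 1382, 299, 43, 39 and 1256 host genes passed in the 5 comparisons, and 2 lists at 10 and 3 at 25 against 5 min. The numbers did not pair the samples, since the correlations of deviations of same-numbered samples ran from -0.132 to 0.153 for host genes and from -0.579 to 0.623 for T7 genes. Not every sample correlated best with its own number. The block ended the calls of the ATP synthase list at 10 against 5 min, T7 gene 19 at 15 against 10 min and SR36_RS21315 at 25 against 20 min, and no other call of a named gene or list that passed.

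Signs of log2 changes turned for these T7 genes. With DESeq2 size factors, in edgeR or in the Wald test, values turned for gene 1.2 (-4.44), gene 10A (-0.70) and gene 17 (-1.23) at 10 against 5 min. They turned for gene 17.5 (0.40), gene 18 (0.63) and gene 0.7 (0.54) at 20 against 15 min. They turned for gene 19.2 (0.52), gene 2 (0.00990), gene 2.5 (0.0128), gene 4.1 (0.0323), gene 4.3 (0.0428), gene 0.3 (0.19), gene 0.7 (0.10), gene 3.5 (0.17) and gene 19 (0.53) at 25 against 20 min. They turned for gene 2 (-2.83), gene 2.5 (-1.45) and gene 5 (-0.0111) at 25 against 5 min. In the Wald test itself, gene 2 at 25 against 20 min was 0.0114, gene 2.5 at 25 against 20 min was 0.0129, gene 4.3 at 25 against 20 min was 0.0427, gene 2 at 25 against 5 min was -2.84, gene 5 at 25 against 5 min was -0.0126. With TMM factors values turned for gene 1.2 (-4.70), gene 10A (-0.97) and gene 17 (-1.50) at 10 against 5 min. Others turned for gene 17.5 (0.15), gene 18 (0.39) and gene 0.7 (0.29) at 20 against 15 min. Others turned for gene 19.2 (0.13) and gene 19 (0.14) at 25 against 20 min. Others turned for gene 2 (-3.48), gene 2.5 (-2.10), gene 3.5 (-0.15), gene 5 (-0.67) and gene 6 (-0.29) at 25 against 5 min. With the total of phage and host counts values turned for gene 1.2 (0.10) and gene 1.3 (0.71) at 25 against 5 min and for gene 1 (0.00228) and gene 1.1 (2.08) at 10 against 5 min. With run 1 alone the sign turned for gene 0.3 (-0.0185) at 20 against 15 min, where leaving out single libraries gave -0.0237 to 0.15.

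Signs also turned for host genes. With host totals alone signs turned for cmk (-0.00905) at 10 against 5 min, rne (-0.0903) at 15 against 10 min, rpoC (0.15), trxA (0.0485) and recB (0.14) at 20 against 15 min and for rne (-0.00487) at 25 against 5 min. With no filter signs turned for rne (-0.0870) at 15 against 10 min and for rne (-0.0534) at 25 against 5 min. With a fit on the 2 times alone signs turned for rpoC (0.00193) at 20 against 15 min. With run 1 alone signs turned for rne (-0.0536) at 15 against 10 min and for rpoC (0.14) at 20 against 15 min. Under run 2 alone signs turned for rne (-0.00166), recB (-0.0156) and dgt (0.11) at 15 against 10 min, trxA (0.0494), recB (0.18) and udk (-0.27) at 20 against 15 min and for udk (0.48) at 25 against 20 min. Under thinning signs turned for dgt (0.0219) at 15 against 10 min, recB (0.24) at 20 against 15 min, recB (-0.0228) at 25 against 20 min and for dgt (0.0385) and cmk (0.31) at 25 against 5 min. Under the DESeq2 Wald test signs turned for rne (-0.00505) at 15 against 10 min. Under the fit without glycogen phosphorylase signs turned for rne (-0.00891) at 15 against 10 min and for rpoC (0.00391) at 20 against 15 min. Leaving out single libraries gave -0.52 to 0.0627 for cmk at 25 against 5 min, -0.23 to 0.30 for recB at 20 against 15 min, -0.15 to 0.000729 for rne at 10 against 5 min, -0.0934 to 0.11 for rne at 15 against 10 min, -0.0852 to 0.0950 for rpoC at 20 against 15 min. It gave -0.00797 to 0.11 for trxA at 25 against 20 min, -0.82 to 0.19 for udk at 15 against 10 min and -0.49 to 0.27 for udk at 25 against 20 min.

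With the total of phage and host counts the median log2 change of host genes was -2.93 at 10 against 5 min and -3.96 at 25 against 5 min. The sign turned for these named genes, first at 10 against 5 min. SR36_RS11880 (-0.56), rpoC (-0.71), aceF (-0.84), rpoB (-0.94), SR36_RS20235 (-0.94), SR36_RS01390 (-0.94), shoB (-1.0), atpC (-1.04), entE (-1.02), SR36_RS14100 (-1.08) and SR36_RS17285 (-1.08) were below 0. sucB (-1.09), recB (-2.41), cmk (-2.52), atpD (-1.12), tisB (-1.16), uvrA (-1.76), acnB (-1.23), ilvC (-1.19), ilvD (-1.37), rbfA (-2.15) and spy (-1.27) were below 0. cpxP (-1.33), flgE (-2.09), poxB (-1.33), katE (-1.49), clpB (-1.48), hslU (-1.96), entD (-1.15), lamB (-1.19), pspB (-2.27), pspD (-2.33) and fusA (-1.50) were below 0. The next genes are those at 25 against 5 min, where SR36_RS16855 (0.37), SR36_RS16070 (0.15) and SR36_RS20235 (0.0206) stayed above 0 and did not pass. SR36_RS12695 (-0.22), SR36_RS20240 (-0.34), SR36_RS09350 (-0.80), lamB (-0.91), SR36_RS14100 (-0.93), sucB (-1.04), yrbL (-1.08), SR36_RS20220 (-1.13), fecI (-1.15), rne (-3.72) and rpoC (-1.18) were below 0. recB (-2.71), atpD (-1.50), atpC (-1.96), atpG (-2.15), atpA (-3.16), rnr (-2.67), rpoB (-2.26), rpoA (-2.47), tisB (-2.06), uvrA (-2.10) and uvrB (-2.88) were below 0. ruvB (-2.93), acnB (-1.63), sucC (-1.63), sucD (-1.67), hisC (-1.09), ilvD (-1.37), hisD (-1.52), ilvC (-1.56), rbfA (-3.53), nusA (-3.54) and cspG (-3.55) were below 0. spy (-1.30), degP (-1.60), cpxP (-1.79), cpxA (-2.40), flgE (-2.20), flgF (-2.22), flgD (-2.32), poxB (-1.29), katE (-1.58), sra (-2.90) and clpB (-2.47) were below 0. entE (-0.74), entB (-1.44), entF (-1.57), entD (-1.88), purH (-1.67), pyrB (-2.24), pspG (-2.95), pspC (-3.04), pspD (-3.17), pspB (-3.18) and infC (-3.29) were below 0. At the other times signs turned for rne (-0.64), rnc (-0.49) and recB (-0.20) at 15 against 10 min and for rne (-0.28) at 20 against 15 min. Depth limits the later times, where host totals were 173840 to 248959 counts per library at 25 min. At 25 against 20 min 46% of simulated host genes lowered by a log2 change of 1 and 72% of those raised by 1 were called. Gene features in place of coding features could not be tried for T7, and for host genes they changed the direction or side of the threshold of none of the values compared.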

Other observations

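The tests of patterns reported here were chosen after the results had been seen.

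Ribosomal protein genes were over-represented among host genes that fell late. Of 53 tested, 18 were among the 40 genes that fell from 15 to 20 min (Fisher's exact p = 4.9e-20) and 31 among the 39 that fell from 20 to 25 min (Fisher's exact p = 2.1e-47), and genes are not independent replicates. A gene with a small SE could pass at a small change, such as rplE at -0.46 (SE 0.09, edgeR adjusted p = 0.00238) from 20 to 25 min. The Fisher p-values may thus partly reflect how readily a fall was detected.

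Over 162 runs of at least 3 neighbouring tested genes on 1 strand with gaps of at most 100 bp (683 genes), genes later in a run had larger log2 changes from 5 to 10 min. The mean rho with gene order was 0.201, positive in 98 runs and negative in 59 (permutation p = 4e-05, adjusted p = 2e-04). It was 0.157 from 5 to 25 min (adjusted p = 0.00333), 0.189 from 5 to 10 min and 0.124 from 5 to 25 min without runs that hold a ribosomal protein gene and 0.224 with gaps of at most 50 bp. It was 0.0685 from 10 to 15 min (adjusted p = 0.198), -0.0870 from 15 to 20 min (adjusted p = 0.119) and 0.0231 from 20 to 25 min (adjusted p = 0.631), none of which passed. A candidate explanation is that transcription begun before infection went on to the ends of operons while fewer new transcripts started, although the 59 runs with a negative value went the other way. Coding length is argued against, since its mean rho with gene order was 0.0225 (permutation p = 0.645).

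In 5 cases 1 library of a time had at least 100 counts of a host gene and stood over 10 times above the other 2. These were SR36_RS12135 in 5 min replicate 2 (165 counts against 2 to 11), SR36_RS14395 in 10 min replicate 3 (15938 counts against 43 to 44), SR36_RS17590 in 15 min replicate 2 (3330 counts against 25 to 43), SR36_RS19440 in 15 min replicate 2 (3150 counts against 21 to 46) and SR36_RS19445 in 15 min replicate 1 (1676 counts against 5 to 7). In each case nearly all counts lay in run 1 of the library, with 2, 10, 10, 19 and 3 in run 2. The 3 genes at 15 min were among the 40 that fell from 15 to 20 min.

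The 6 libraries of a comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For each count of genes that passed edgeR's test 1 of the 10 splits, the real one, gave as many. Every other split mixes 2 libraries of 1 time with 1 of the other. The difference between the times then enters the spread within the groups, which by itself lowers the count. The counts of the other splits therefore cannot show what chance would give. For host genes the real count and the highest of the other splits were 1395 and 0 at 10 against 5, 303 and 4 at 15 against 10, 42 and 3 at 20 against 15, 41 and 1 at 25 against 20 and 1255 and 1 at 25 against 5 min. For T7 genes the real counts were 55, 54, 31, 27 and 56 and the highest other count was 0 in each comparison. For gene lists in camera 9 of the 10 splits gave at least as many at 25 against 5 min (real 2, highest other 4) and 6 of 10 at 10 against 5 min (real 3, highest other 6). The mixed splits keep part of the difference between the times, so these numbers decide nothing about chance either.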
